A study of Homo sapiens with 12 samples.

How the data were processed

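RNA of U-87 MG cells, an established human glioma line, was measured on 12 Affymetrix expression arrays. The cells carried a stably transfected short hairpin RNA against p105 (shp105) or a control hairpin (shControl) and received temozolomide (TMZ) or the vehicle DMSO. This gave 4 groups of 3 arrays. The deposited values are log2 expression levels per probe set, 1 column per array. RMA and Affymetrix Power Tools were used to make them, per the submitters' processing notes, which give neither versions nor the role of each. The genome build, the probe annotation release and any filter of the authors are not given in the sources used here. All 54675 probe sets had a value on all 12 arrays, and no pair of arrays held identical values.

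Probe sets were given gene symbols from a probe table for this array and the RefSeq gene table of assembly GCF_000001405.40 (GRCh38.p14). Exactly 1 gene symbol was found for 41097 probe sets. Of these 41097, 54 had an Entrez identifier absent from the RefSeq table and kept the symbol of the probe table. The 1801 probe sets with several symbols and the 11777 without a name were not used for genes. Of the probe sets of a gene, the one with the highest mean over all 12 arrays stood for it, which left 19775 genes. No filter on dim genes was applied. The number of arrays limits the precision stated here.

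The 5 comparisons each used limma's moderated test on one fit of the 4 group means over all 12 arrays (lmFit and eBayes): TMZ minus DMSO in each line, shp105 minus shControl under each treatment, and the difference of both TMZ responses. Adjusted p values are Benjamini-Hochberg values over the 19775 genes, and genes under 0.05 are called. Errors of log2 differences are the standard errors of that fit, and tests are 2-sided. Similarity of responses was measured by Pearson's r and Spearman's rho across genes, without a p, since genes are not independent replicates. Spike-in levels were compared by exact 2-sided permutation tests.

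The groups, the tests, the 19 gene lists, the rule for naming genes and most alternatives were fixed before the data were examined. The lists hold 514 distinct genes, of which 465 were measured. Each list was tested with limma's camera at its preset inter-gene correlation of 0.01, adjusted over the 19 lists of a comparison. The same test with an estimated correlation and the test fry stand beside it. Named in each comparison are NFKB1, the 10 called genes with the largest increase and the 10 with the largest decrease among those whose groups share no range, and up to 4 called members of each list by smallest p. Where a list has no called member, its member with the smallest p may be given as a value. Where fewer than 10 genes are called, the 5 with the smallest p are given as values. MGMT, CDKN1A, MDM2, RELA and CA2 are given in any comparison. Of the named genes with several probe sets, all probe sets moved the same way for 16 of 24 genes in the TMZ response of shControl cells and for 13 of 25 in that of shp105 cells. For the difference of both responses it was 9 of 16, and between the lines 36 of 50 in DMSO and 40 of 55 in TMZ.

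The fit was tested on simulated data with the real gene levels. A simulated log2 change of 0.6 was recovered for 92% of 50 genes in the TMZ response of shControl cells, 88% in that of shp105 cells, 88% between the lines under either treatment, and 62% for the difference of responses. At 0.4 the shares were 60%, 66%, 62% (lines in DMSO), 54% (lines in TMZ) and 10%. Camera called a list shifted by 0.15 and 0 of 14 unshifted lists. The simulated genes varied independently of each other, so this says nothing about false calls that correlated genes can bring.

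The alternatives were another gene summary (the mean of a gene's probe sets, or each probe set on its own), genes below the median level left out, median centring or quantile normalization on top of the deposited values, array weights, eBayes with trend and robust fitting, an ordinary linear model, only the compared groups in the fit, the replicate number as a block, stricter thresholds, and each array left out in turn. A fit with the spike-in level as a covariate was added after the spike-in levels had been seen. R 4.3.3 with limma 3.58.1 and the data.table package, version 1.17.8, made the tables. Python 3.11.15 with matplotlib 3.10.9 and numpy 2.4.6 drew the plots.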

Results

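Expression was measured in U-87 MG glioma cells with a stably transfected hairpin against p105 (shp105) or a control hairpin (shControl). p105 is the product of NFKB1 and the precursor of the NF-kB subunit p50. Each line was treated for 16 h with 100 uM TMZ, a DNA-methylating drug given against glioma, or with DMSO. The series asks how cells with proficient and deficient NF-kB answer the drug. Each of the 4 groups had 3 arrays, so n = 3 stands behind every group mean here. The median log2 level of an array lay between 5.04 and 5.09. Across genes, 2 arrays of the same group correlated at 0.997 to 0.998 and arrays of different lines at 0.990 to 0.992. The labels call the replicates biological but do not say whether they come from separate transfections, so the p-values measure only the spread between these samples.

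NFKB1, the targeted gene, was read by 1 probe set. Its mean log2 level was 7.32 (SD 0.09) in shControl cells with DMSO and 7.41 (SD 0.11) with TMZ. In shp105 cells it was 7.20 (SD 0.06) with DMSO and 7.16 (SD 0.05) with TMZ. The line difference, shp105 minus shControl, was -0.12 (SE 0.07, adjusted p = 0.260) in DMSO, which did not pass. In TMZ it was -0.25 (SE 0.07, adjusted p = 0.0204), which passed. That call was lost without shp105_TMZ replicate 1 (adjusted p = 0.0600), without shp105_TMZ replicate 3 (0.0585), without shControl_TMZ replicate 1 (0.0903) and without shControl_TMZ replicate 2 (0.0684). It was also lost with only the compared groups in the fit (-0.25, adjusted p = 0.0558) and with the spike-in level as a covariate (-0.19, adjusted p = 0.556). Over all alternatives its adjusted p ran from 0.00505 to 0.556. TMZ left NFKB1 uncalled in shControl cells (0.09, adjusted p = 0.669) and in shp105 cells (-0.04, adjusted p = 0.840). The difference of both line differences was -0.13 (adjusted p = 0.879).

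Between the lines in DMSO, 21 of 37 measured NF-kB target genes were lower in shp105 cells and 1 was higher. IL1B, the cytokine interleukin-1 beta, was lower by a log2 difference of -2.76 (SE 0.07, adjusted p = 2.99e-10), and CXCL8, a neutrophil chemokine, by -2.24 (SE 0.12, adjusted p = 1.10e-07). Larger still were differences outside any NF-kB list. The long noncoding RNA UCA1 was higher by 6.52 (SE 0.13) and the transcription factor SOX4 by 6.05 (SE 0.11), while GUCY1B1, a subunit of soluble guanylate cyclase, was lower by -5.25 (SE 0.10). In total 3937 of 19775 genes differed, 1650 higher and 2287 lower in shp105 cells, and 350 of them by at least 2-fold.

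Of 37 measured NF-kB target genes, 21 were lower, 1 was higher and 15 did not pass. With p adjusted over the list alone, 23 were lower and 1 higher. The list's median difference was -0.46, with a camera adjusted p of 7.30e-11 and an adjusted p = 0.0134 with an estimated correlation. NFKBIZ, an atypical IkB protein, was lower by -1.42 (SE 0.07) and the cytokine LIF by -1.01 (SE 0.05). The single higher target, GADD45B, a stress-inducible signalling protein, differed by 0.64 and was looked up after its value was seen. Among 26 NF-kB pathway components 7 were lower and 1 higher (18 not passing; adjusted over the list alone 7 and 1; median -0.12, camera adjusted p = 0.00795, adjusted p = 0.198 with an estimated correlation). RELB, the non-canonical subunit, was lower by -0.81 (SE 0.10) and TNIP1, an inhibitor of the pathway, by -0.56 (SE 0.06). MAP3K14, the kinase of the non-canonical branch, was higher by 0.65 (SE 0.05). RELA, the main activating subunit, was not called (-0.12, adjusted p = 0.135).

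**Figure D1:**
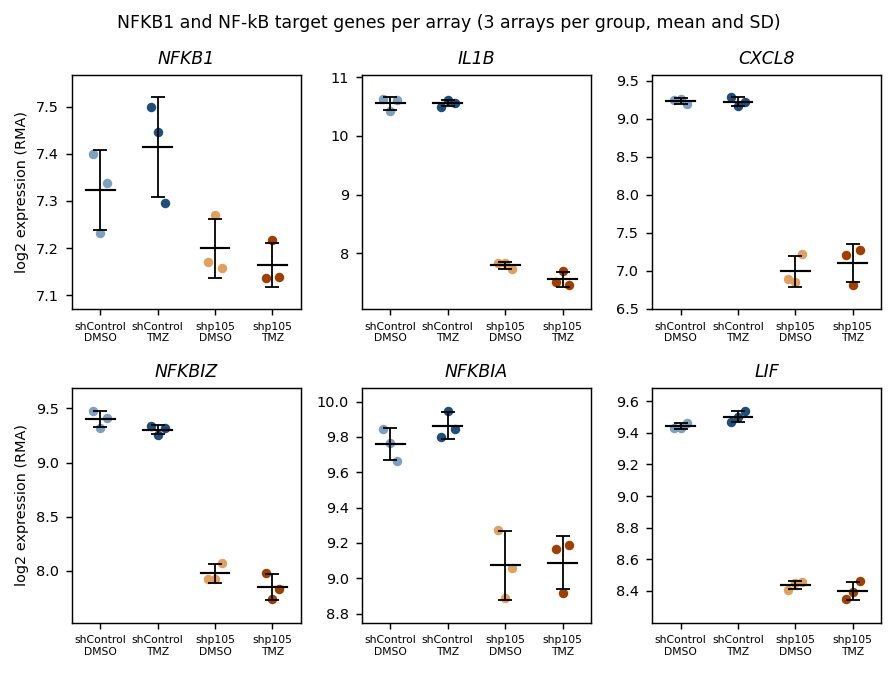
Log2 expression of NFKB1 and of 5 NF-kB target genes (IL1B, CXCL8, NFKBIZ, NFKBIA, LIF) on each of the 12 arrays, by group; points are arrays, bars are group means with SD (n = 3). IL1B lay at 10.55 in shControl and 7.80 in shp105 cells with DMSO, while NFKB1 lay at 7.32 and 7.20.

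Extracellular matrix genes differed in both directions, 17 higher and 10 lower of 35 (8 not passing; adjusted over the list alone 17 and 11). Higher were LAMA4, a laminin chain, by 1.73 (SE 0.09), the collagen cross-linking enzyme LOXL2 by 1.29 (SE 0.05) and the gelatinase MMP2 by 0.94 (SE 0.05). The collagenase MMP1 was lower by -1.42 (SE 0.06). The list's median was 0.18 (camera adjusted p = 0.000921, adjusted p = 0.215 with an estimated correlation). Of 26 hypoxia and glycolysis genes 10 were higher and 2 lower (14 not passing; adjusted over the list alone 10 and 2), with the glucose transporter SLC2A1 at 0.85 (SE 0.08) and the mitochondrial kinase PDK1 at 0.84 (SE 0.08). This list's median was 0.10 (camera adjusted p = 0.000618, adjusted p = 0.108 with an estimated correlation). Of 19 cholesterol synthesis genes 9 were lower and 1 higher (9 not passing; adjusted over the list alone 11 and 1), among them the synthesis enzymes MSMO1 at -0.64 (SE 0.10) and SQLE at -0.50 (SE 0.06). The median was -0.17 (camera adjusted p = 0.00144, adjusted p = 0.160 with an estimated correlation).

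Cell-cycle lists were slightly lower in shp105 cells. Of 31 DNA replication genes 14 were lower, 1 was higher and 16 did not pass (adjusted over the list alone 16 and 1). Ribonucleotide reductase subunit RRM2 was at -0.34 (SE 0.04), and thymidylate synthase, TYMS, was the higher one at 0.61 (SE 0.06). The median was -0.16 (camera adjusted p = 0.00141, adjusted p = 0.198 with an estimated correlation). Of 30 mitosis genes 12 were lower and 2 higher (16 not passing; adjusted over the list alone 13 and 3), such as the spindle kinesin KIF11 at -0.37 (SE 0.07) and another mitotic kinesin, KIF20A, at 0.31 (SE 0.05). The median was -0.12 (camera adjusted p = 0.00302, adjusted p = 0.198 with an estimated correlation).

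Members of the p53 target list went both ways, 5 higher and 9 lower of 35 (adjusted over the list alone 6 and 9; camera adjusted p = 0.605). The cell-cycle inhibitor CDKN1A was lower by -0.40 (SE 0.06), the death receptor FAS by -0.47 (SE 0.06) and TRIM22 by -0.76 (SE 0.06), while PMAIP1, a pro-apoptotic BCL2 relative, was higher by 0.91 (SE 0.10). The p53 ligase MDM2, which marks p53 for degradation, was higher by 0.33 (SE 0.07). The BCL2 family had 3 higher and 2 lower of 16 (camera adjusted p = 0.330). Of 22 mesenchymal glioma markers 8 were higher, among them the secreted glycoprotein CHI3L1 by 2.21 (SE 0.13), and 8 were lower, among them the receptor IL1R1 by -1.51 (SE 0.09; camera adjusted p = 0.886). Of 21 proneural markers 2 were higher, SOX4 and the glial transcription factor OLIG2 at 1.22 (SE 0.15), and 2 lower (camera adjusted p = 0.605). For both marker lists the median was slightly negative and the mean positive. The counts adjusted over the list alone, higher and lower, were 4 and 2 for the BCL2 family, 9 and 10 for mesenchymal and 2 and 2 for proneural markers.

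Repair lists passed no camera test in DMSO. Fry gave an adjusted p of 0.0132 for alkylation and base repair genes and of 0.000520 for recombination and Fanconi genes. Fry also passed other lists that camera did not call. These were p53 targets (fry adjusted p = 0.0132), proneural markers (0.00109), epithelial markers (0.0159) and the BCL2 family (0.0337). Of 21 alkylation, mismatch and base excision repair genes 6 were lower and 1 higher (camera adjusted p = 0.160), and of 22 homologous recombination and Fanconi genes 6 were lower and 1 higher (camera adjusted p = 0.0768). MGMT, which removes the methyl group that TMZ leaves on guanine, was near background in all 4 groups, at log2 levels between 3.38 and 3.67, and differed by -0.23 (adjusted p = 0.212). CA2, carbonic anhydrase II, was lower by -1.61 (SE 0.08). Of 24 immediate early genes 6 were higher and 7 lower (camera adjusted p = 0.714), with the ERK phosphatase DUSP6 at -1.13 (SE 0.07) and the matricellular gene CCN2 at 0.85 (SE 0.06). Interferon genes had 6 higher and 2 lower of 30 (camera adjusted p = 0.364), and stress-response genes 4 higher and 3 lower of 28 (camera adjusted p = 0.617). Leukocyte markers had 1 higher and 2 lower of 20 (camera adjusted p = 0.886), epithelial markers 5 higher and 1 lower of 19 (camera adjusted p = 0.0768), and ribosomal protein genes 1 higher of 23 (camera adjusted p = 0.886). The counts adjusted over the list alone, higher and lower, were 1 and 7 for base repair, 1 and 9 for recombination, 6 and 8 for immediate early, 6 and 3 for interferon, 5 and 3 for stress, 1 and 2 for leukocyte, 5 and 1 for epithelial and 0 and 0 for ribosomal genes. The 3' minus 5' signal of GAPDH, a sign of RNA quality, was higher by 0.11 in shp105 cells with DMSO and by 0.10 with TMZ (exact p = 0.1 each, the smallest that 3 against 3 arrays can give). That of ACTB differed by 0.05 with DMSO (exact p = 0.6) and by 0.21 with TMZ (exact p = 0.1).

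Other genes with the largest differences were higher for LIMCH1, a regulator of actomyosin, by 5.75 (SE 0.10), the mesenchymal cadherin CDH11 by 5.46 (SE 0.10), the neuropeptide gene NMU by 4.52 (SE 0.08) and the receptor phosphatase PTPRF by 3.63 (SE 0.25). They were lower for the splicing regulator MBNL3 by -4.34 (SE 0.12), the long noncoding RNA HOTAIR by -4.30 (SE 0.11), the argininosuccinate synthase ASS1 by -3.93 (SE 0.11), the chemokine CXCL14 by -3.73 (SE 0.08) and the linker histone H1-2 by -2.81 (SE 0.07). SOX4, LIMCH1, CDH11, NMU, PTPRF and OLIG2 stood at 2.93, 3.48, 3.22, 4.08, 4.08 and 4.05 in shControl cells, and GUCY1B1, MBNL3 and HOTAIR at 3.31, 3.21 and 3.26 in shp105 cells. Control probe sets for sequences absent from the cells had levels of 2.33 to 4.30, so these differences start from background. The arrays of the lines also differed in their hybridization spike-ins, which averaged 11.35 (SD 0.09) in shp105 and 10.87 (SD 0.05) in shControl cells with DMSO. Their median log2 levels were alike, between 5.04 and 5.09. With the spike-in level as a covariate 483 genes were called, while the median size of the 3937 differences went from 0.36 to 0.37 and their standard error rose 2.55-fold.

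Under TMZ the lines differed in much the same genes and by similar amounts. UCA1 was higher in shp105 cells by 7.23 (SE 0.13), SOX4 by 5.87 (SE 0.11) and the cancer-testis gene SAGE1 by 3.89 (SE 0.16), while GUCY1B1 was lower by -5.24 (SE 0.10) and IL1B by -3.00 (SE 0.07). SOX4 and SAGE1 stood at 2.96 and 3.04 in shControl cells and GUCY1B1 at 3.33 in shp105 cells, so these 3 differences start from background. There were 4166 called genes, 1993 higher and 2173 lower, and 346 differed by at least 2-fold. Higher under both treatments were 1306 genes, where 166 would be shared by chance, and lower under both were 1619, against 251 by chance. Of the 5174 genes called under either treatment, 4959 had the same sign under both, and 4 were called in opposite directions. The line differences under DMSO and TMZ, which share no arrays, correlated across genes at r = 0.90 (rho = 0.64).

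NF-kB targets stayed lower in TMZ, 22 of 37 lower and 1 higher (14 not passing; adjusted over the list alone 24 and 2). Their median was -0.41, with a camera adjusted p of 1.26e-09 and an adjusted p = 0.0198 with an estimated correlation. CXCL8 was at -2.12 (SE 0.12), NFKBIZ at -1.45 (SE 0.07) and LIF at -1.10 (SE 0.05). Of the 26 pathway components 6 were lower, among them NFKBIA, the canonical inhibitor, at -0.78 (SE 0.10), and 1 was higher (adjusted over the list alone 7 and 1; camera adjusted p = 0.117). RELA was not called (-0.15, adjusted p = 0.0612).

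Genes of the integrated stress and unfolded protein response also differed in TMZ, with 14 of 28 genes higher and 1 lower (13 not passing; adjusted over the list alone 15 and 1). The secreted glycoprotein STC2 was higher by 0.79 (SE 0.07), the mTOR inhibitor DDIT4 by 0.54 (SE 0.06), the transcription factor DDIT3, also known as CHOP, by 0.46 (SE 0.06) and the pseudokinase TRIB3 by 0.42 (SE 0.06). The median was 0.18 (camera adjusted p = 0.000106, adjusted p = 0.0540 with an estimated correlation). Interferon genes had 8 higher and 3 lower of 30 (adjusted over the list alone 9 and 4), with the antiviral genes MX2 at 0.79 (SE 0.12) and OAS3 at 0.53 (SE 0.09). Their median was 0.15 (camera adjusted p = 0.0338, adjusted p = 0.395 with an estimated correlation). That camera call was lost without shp105_TMZ replicate 2 (adjusted p = 0.106) and without shControl_TMZ replicate 1 (0.0791).

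Matrix, hypoxia, cholesterol and mitosis genes differed in TMZ as they had in DMSO. Extracellular matrix genes were 17 higher and 10 lower of 35 (adjusted over the list alone 18 and 11; median 0.18, camera adjusted p = 0.00346, adjusted p = 0.395 with an estimated correlation). Hypoxia genes were 8 higher and 1 lower of 26 (adjusted over the list alone 10 and 1; median 0.10, camera adjusted p = 0.000632, adjusted p = 0.0889 with an estimated correlation). Cholesterol genes were 8 lower of 19 (adjusted over the list alone 9; median -0.14, camera adjusted p = 0.00637, adjusted p = 0.168 with an estimated correlation), with ACAT2, an acetyl-CoA acetyltransferase, at -0.60 (SE 0.10). Mitosis genes were 13 lower and 1 higher of 30 (adjusted over the list alone 14 and 1; median -0.12, camera adjusted p = 0.000240, adjusted p = 0.154 with an estimated correlation), with the cyclin CCNB1 at -0.39 (SE 0.05) and the kinase AURKA at -0.30 (SE 0.05). Ribosomal protein genes, kept as a sign of RNA quality, had 2 higher of 23 (adjusted over the list alone 2; median 0.05, camera adjusted p = 0.0385, adjusted p = 0.438 with an estimated correlation). The ribosomal camera call was lost without shp105_TMZ replicate 2 (adjusted p = 0.117), shControl_TMZ replicate 1 (0.0544) or shControl_TMZ replicate 3 (0.118).

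The other lists passed no camera test between the lines in TMZ. Several of them passed with fry: immediate early genes (fry adjusted p = 0.000902), proneural markers (0.00176), NF-kB components (0.00202) and recombination genes (0.00240). So did p53 targets (0.00333), epithelial markers (0.00663), DNA replication genes (0.00843) and the BCL2 family (0.0379). The values that follow are those of camera. DNA replication genes were 1 higher and 9 lower of 31 (camera adjusted p = 0.0961), repair genes for alkylation and base damage 2 higher and 4 lower of 21 (0.478), and recombination genes 2 higher and 5 lower of 22 (0.289). The p53 list had 4 higher and 10 lower of 35 (0.376), with CDKN1A at -0.36 (SE 0.06), FAS at -0.43 (SE 0.06) and the apoptosis inhibitor TRIAP1 at 0.35 (SE 0.05). MDM2 was not called (0.20, adjusted p = 0.0837), and 2 of its dimmer probe sets stood at -0.35 and -0.34. The BCL2 family had 3 higher and 2 lower of 16 (0.340), with the pro-apoptotic BAX at -0.44 (SE 0.08). Mesenchymal markers were 7 higher and 8 lower of 22 (0.852), with CHI3L1 at 2.96 (SE 0.13), and proneural markers 3 higher and 3 lower of 21 (0.744). Immediate early genes were 5 higher and 8 lower of 24 (0.245), with the transcription factor EGR1 at -1.10 (SE 0.08). Leukocyte markers were 1 higher and 2 lower of 20 (0.744), and epithelial markers 3 higher and 1 lower of 19 (0.301), with the keratin KRT7 at 1.30 (SE 0.08). Each count here has its counterpart adjusted over the list alone, higher and lower: replication 1 and 10, base repair 2 and 5, recombination 2 and 6, p53 targets 6 and 13, BCL2 family 4 and 2, mesenchymal 7 and 8, proneural 3 and 3, immediate early 6 and 10, leukocyte 1 and 2, and epithelial 3 and 1. CA2 was lower by -1.08 (SE 0.08) and MGMT was not called (0.04, adjusted p = 0.870). Spike-ins averaged 11.53 (SD 0.12) in shp105 and 11.18 (SD 0.10) in shControl cells with TMZ, and with their level as a covariate 997 genes were called.

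**Figure D2:**
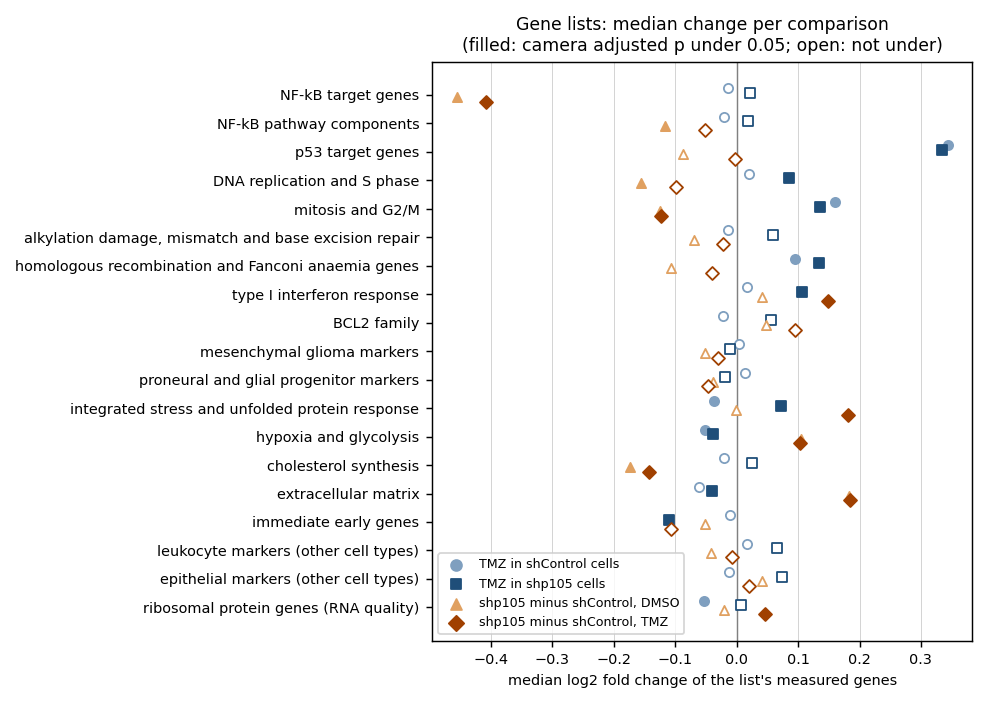
Median log2 difference of each of the 19 gene lists in the 4 comparisons of groups. NF-kB target genes lay at -0.46 and -0.41 between the lines, and p53 target genes at 0.34 and 0.33 after TMZ in shControl and shp105 cells.

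In shControl cells, 16 h of TMZ raised genes that p53 is known to activate. GDF15, a stress cytokine, rose by a log2 change of 1.14 (SE 0.07, adjusted p = 4.47e-05), CDKN1A by 0.88 (SE 0.06, adjusted p = 4.47e-05) and DDB2, a DNA damage sensor, by 0.68 (SE 0.06, adjusted p = 0.000338). The histone gene H2BC12 and the chaperone gene HSPA5 fell. In total 73 of 19775 genes changed, 50 higher and 23 lower, and 1 of them, GDF15, by 2-fold or more.

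Of 35 measured p53 targets 15 rose, 0 fell and 20 did not pass, and 29 rose when adjusted over the list alone. The median change was 0.34 (camera adjusted p = 2.66e-42, adjusted p = 1.35e-05 with an estimated correlation). PTCHD4, a patched-like membrane protein, rose by 0.95 (SE 0.13), TP53INP1, a p53-induced nuclear protein, by 0.72 (SE 0.10), MDM2 by 0.61 (SE 0.07), PLK2, a polo-like kinase, by 0.54 (SE 0.05) and BAX by 0.43 (SE 0.08). Of 30 mitosis genes 1 rose, the kinetochore motor CENPE, by 0.36 (SE 0.05). Another count, adjusted over the list alone, was 19, and the median was 0.16 (camera adjusted p = 4.46e-18, adjusted p = 0.00484 with an estimated correlation). Of 22 recombination and Fanconi genes 1 rose, the helicase BLM, by 0.29 (SE 0.05). There were 2 risers adjusted over the list alone, with a median of 0.09 (camera adjusted p = 0.000393, adjusted p = 0.0269 with an estimated correlation).

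**Figure D3:**
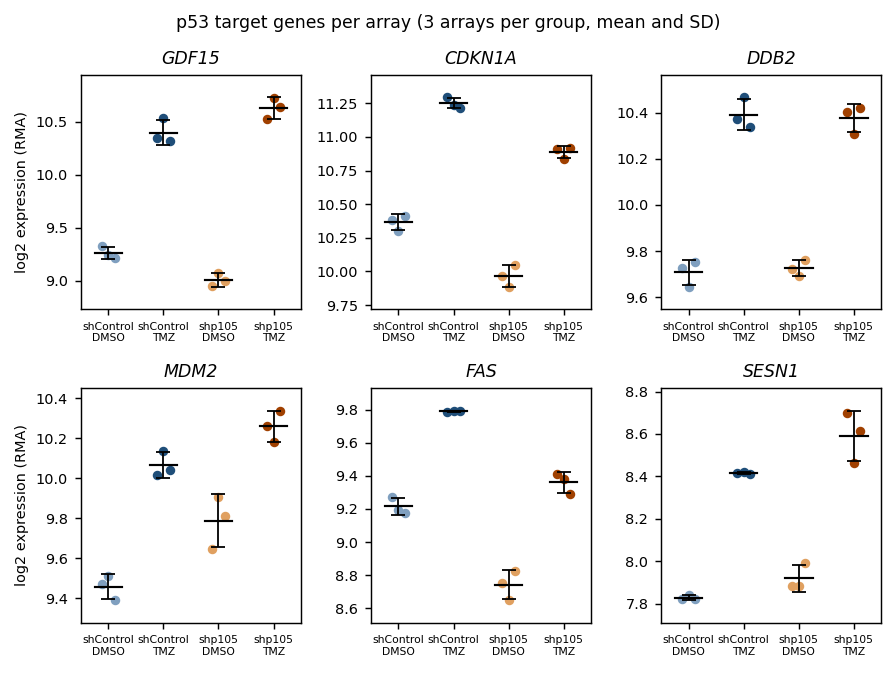
Log2 expression of 6 p53 target genes (GDF15, CDKN1A, DDB2, MDM2, FAS, SESN1) on each of the 12 arrays, by group; points are arrays, bars are group means with SD (n = 3). GDF15 went from 9.26 to 10.40 with TMZ in shControl cells and from 9.01 to 10.63 in shp105 cells.

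Of 28 integrated stress and unfolded protein response genes 2 fell and 26 did not pass. These were HERPUD1, a protein of endoplasmic-reticulum-associated degradation, at -0.48 (SE 0.07), and HSPA5, the chaperone BiP, at -0.28 (SE 0.05). Counts adjusted over the list alone were 6 lower and 1 higher, with a median of -0.04 (camera adjusted p = 0.00686, adjusted p = 0.137 with an estimated correlation). The camera call was lost without shControl_DMSO replicate 1 (adjusted p = 0.0724) and without shControl_TMZ replicate 3 (0.0589). Hypoxia genes had 0 of 26 called in limma (2 lower adjusted over the list alone), a median of -0.05 and a camera adjusted p of 0.0229 (adjusted p = 0.224 with an estimated correlation). This camera call was lost without the same arrays, at 0.0825 and 0.177. Ribosomal protein genes, a sign of RNA quality, had 0 of 23 called and 0 adjusted over the list alone, a median of -0.05 and a camera adjusted p of 0.00169 (adjusted p = 0.555 with an estimated correlation). The 3' minus 5' signal of ACTB, another sign of RNA quality, differed by -0.17 between TMZ and DMSO (exact p = 0.1, the smallest that 3 against 3 arrays can give). That of GAPDH differed in the other direction, by 0.05 (exact p = 0.1).

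Outside the lists, S1PR3, a sphingosine-1-phosphate receptor, rose by 0.64 (SE 0.09), TSGA10, a testis gene, by 0.60 (SE 0.08) and the semaphorin receptor PLXNB2 by 0.59 (SE 0.07). The noncoding transcript DNAJC3-DT fell by 0.73 (SE 0.12), the histone genes H2BC12 by 0.69 (SE 0.06), H2BC6 by 0.65 (SE 0.11) and H2BC12L by 0.63 (SE 0.07), and DEPP1, a FOXO-regulated gene, by 0.62 (SE 0.10). No NF-kB list was called: 0 of 37 targets (1 adjusted over the list alone, camera adjusted p = 0.824) and 0 of 26 components (0 adjusted over the list alone, 0.824) were called. The target with the smallest p, the plasminogen activator PLAU, had 0.24 (adjusted p = 0.0701). RELA stood at 0.02 (adjusted p = 0.948), CA2 at 0.03 (adjusted p = 0.942) and MGMT at -0.28 (adjusted p = 0.378).

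The remaining lists passed no camera test in this comparison. The BCL2 family had 1 riser of 16, BAX (camera adjusted p = 0.582). No member was called among DNA replication genes (0.724), alkylation and base repair genes (0.824), interferon genes (0.450), mesenchymal markers (0.824), proneural markers (0.974), cholesterol genes (0.641), matrix genes (0.0756), immediate early genes (0.450), leukocyte markers (0.469) or epithelial markers (0.965). When adjusted over the list alone, 2 BCL2 family genes, 1 replication gene and 3 base repair genes were higher, and 2 base repair, 1 cholesterol and 1 epithelial gene were lower. Leaving out 1 array lowered the count of 73 to 29, 16 and 20 (shControl_DMSO replicates 1, 2 and 3) and to 24, 16 and 19 (shControl_TMZ replicates 1, 2 and 3). Spike-ins averaged 11.18 with TMZ and 10.87 with DMSO, and with their level as a covariate 0 genes were called, since the standard error of the 73 genes rose 1.85-fold while their median size stayed at 0.41.

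In shp105 cells TMZ raised p53 targets as well. GDF15 rose by 1.62 (SE 0.07, adjusted p = 1.69e-06), CDKN1A by 0.92 (SE 0.06, adjusted p = 2.80e-05) and SESN1, a stress-induced sestrin, by 0.67 (SE 0.06, adjusted p = 0.000901). Asparagine synthetase, ASNS, rose by 0.36 (SE 0.06, adjusted p = 0.0218). In total 171 of 19775 genes changed, 128 higher and 43 lower, and 1 of them, GDF15, by 2-fold or more.

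Of 35 p53 targets 16 rose, 0 fell and 19 did not pass; adjusted over the list alone 26 rose. The median was 0.33 (camera adjusted p = 3.37e-27, adjusted p = 7.52e-05 with an estimated correlation). DDB2 rose by 0.65 (SE 0.06) and MDM2 by 0.47 (SE 0.07). Of 30 mitosis genes 2 rose, the phosphatase CDC25C by 0.37 (SE 0.07) and CENPE by 0.26 (SE 0.05). There were 13 risers adjusted over the list alone, with a median of 0.14 (camera adjusted p = 3.37e-08, adjusted p = 0.0379 with an estimated correlation). Of 22 recombination and Fanconi genes 2 rose, BLM by 0.37 (SE 0.05) and the recombination translocase RAD54B by 0.32 (SE 0.06). There were 5 risers adjusted over the list alone, with a median of 0.13 (camera adjusted p = 0.000339, adjusted p = 0.0379 with an estimated correlation).

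Of 28 stress-response genes 4 rose and 24 did not pass: ASNS, the transcription factor ATF3 by 0.37 (SE 0.06), the serine synthesis enzyme PHGDH by 0.26 (SE 0.05) and the glutathione-degrading CHAC1 by 0.39 (SE 0.08). Counts adjusted over the list alone were 8 higher and 1 lower, with a median of 0.07 (camera adjusted p = 0.00137, adjusted p = 0.0612 with an estimated correlation). Of 31 DNA replication genes 1 rose, RRM2, by 0.42 (SE 0.04). Counts adjusted over the list alone were 6 higher and 2 lower, with a median of 0.08 (camera adjusted p = 0.0138, adjusted p = 0.285 with an estimated correlation). The replication camera call was lost without shp105_DMSO replicate 1 (adjusted p = 0.0647) and without shp105_TMZ replicate 3 (0.0689). Of 30 interferon genes 1 rose, the interferon regulator IRF7, by 0.37 (SE 0.07). Adjusted over the list alone 4 rose, with a median of 0.11 (camera adjusted p = 0.00264, adjusted p = 0.155 with an estimated correlation).

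Of 24 immediate early genes 1 rose, ATF3, and 2 fell, the transcription factor KLF4 by 0.31 (SE 0.06) and DUSP6 by 0.36 (SE 0.07). Counts adjusted over the list alone were 10 lower and 1 higher, with a median of -0.11 (camera adjusted p = 0.000145, adjusted p = 0.0612 with an estimated correlation). Hypoxia genes had 0 of 26 called in limma (2 lower adjusted over the list alone), with a median of -0.04 (camera adjusted p = 0.0138, adjusted p = 0.155 with an estimated correlation). Matrix genes had 0 of 35 called (2 higher and 2 lower adjusted over the list alone), with a median of -0.04 (camera adjusted p = 0.0328, adjusted p = 0.577 with an estimated correlation). The matrix camera call was lost without shp105_DMSO replicate 2 (adjusted p = 0.208) or 3 (0.0529) and without shp105_TMZ replicate 1 (0.174) or 3 (0.0566).

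CA2 rose by 0.56 (SE 0.08) in shp105 cells. The neuronal adhesion gene ASTN2 rose by 0.73 (SE 0.09), S1PR3 by 0.67 (SE 0.09) and the spermatogenesis gene SPATS1 by 0.86 (SE 0.11). IFITM10, which carries the name of the IFITM transmembrane family, fell by 0.56 (SE 0.06), the pentraxin PTX3 by 0.50 (SE 0.08) and H2BC12 by 0.49 (SE 0.06). The arrestin-domain gene ARRDC3 fell by 0.43 (SE 0.08) and the nuclear receptor NR2F1 by 0.41 (SE 0.07). The repair glycosylase UNG fell by 0.35 (SE 0.06) and the exonuclease EXO1 rose by 0.34 (SE 0.07), the 2 called genes among 21 for alkylation and base repair (camera adjusted p = 0.234). The NF-kB lists had 0 of 37 targets and 0 of 26 components called (0 and 1 adjusted over the list alone; camera adjusted p = 0.801 and 0.289). RELB, the target with the smallest p, stood at 0.36 (adjusted p = 0.109), RELA at -0.01 (adjusted p = 0.932) and MGMT at -0.02 (adjusted p = 0.948).

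The remaining lists passed no camera test here. Proneural markers had 1 called member of 21, the RNA-binding gene MSI1, which fell by 0.33 (SE 0.06) at a level near background (0.771). No member was called in the BCL2 family (0.787) or among mesenchymal (0.567), leukocyte (0.771) and epithelial markers (0.801), cholesterol genes (0.771) or ribosomal protein genes (0.802). When adjusted over the list alone, 4 base repair, 2 mesenchymal, 2 proneural and 1 epithelial gene were higher, and 1 base repair, 1 mesenchymal, 2 proneural, 3 cholesterol and 1 epithelial gene were lower. Leaving out 1 array changed the count of 171 to 52, 49 and 76 (shp105_DMSO replicates 1, 2 and 3) and to 188, 81 and 86 (shp105_TMZ replicates 1, 2 and 3). Spike-ins averaged 11.53 with TMZ and 11.35 with DMSO, and with their level as a covariate 7 genes were called, since the standard error of the 171 genes rose 1.37-fold while their median size stayed at 0.37.

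Most genes called after TMZ in either line moved the same way in both, and of the 19 lists the integrated stress and unfolded protein response differed with the smallest camera p. Across genes the responses, which share no arrays, correlated at r = 0.33 (rho = 0.31). In both lines 35 genes rose, where 0.32 would be shared by chance, and 6 fell, where 0.05 would be. Of the 203 genes called in either line 182 moved the same way in both, and 0 were called in opposite directions. The stress list moved up in shp105 relative to shControl cells, with positive differences for 24 of 28 genes and a median of 0.13.

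For that list the camera adjusted p was 3.58e-09, and the adjusted p = 0.0119 with an estimated correlation. When adjusted over the list alone, 5 members passed. DDIT4 had -0.31 with TMZ in shControl and 0.28 in shp105 cells, a difference of 0.59 (SE 0.08, adjusted p = 0.104). DDIT3 had -0.30 and 0.27, a difference of 0.56 (SE 0.08, adjusted p = 0.136). CHAC1 differed by 0.53 (adjusted p = 0.381), ASNS by 0.24 (adjusted p = 0.708) and HERPUD1 by 0.46 (adjusted p = 0.438). CHAC1, ASNS and HERPUD1 are given outside the naming rule for this comparison. With TMZ, CHAC1 and ASNS were called in shp105 cells and HERPUD1 in shControl cells. All of these differences are larger than the list's median of 0.13, so they do not stand for the list as a whole. Ribosomal protein genes, a sign of RNA quality, also moved up, with a median difference of 0.08 (camera adjusted p = 0.00995, adjusted p = 0.663 with an estimated correlation).

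**Figure D4:**
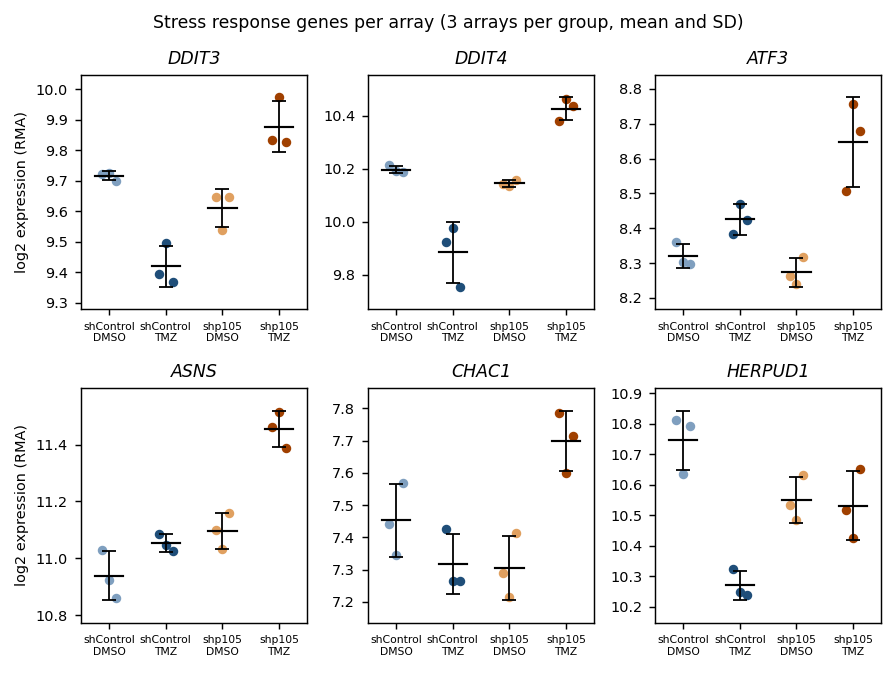
Log2 expression of 6 stress-response genes (DDIT3, DDIT4, ATF3, ASNS, CHAC1, HERPUD1) on each of the 12 arrays, by group; points are arrays, bars are group means with SD (n = 3). DDIT4 went from 10.20 to 9.88 with TMZ in shControl cells and from 10.15 to 10.43 in shp105 cells. The 6 genes are a choice from the 28 of the list, whose median difference of responses was 0.13.

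DNA replication genes had a median difference of 0.06 (camera adjusted p = 0.0465, adjusted p = 0.663 with an estimated correlation) and immediate early genes one of -0.06 (camera adjusted p = 0.0113, adjusted p = 0.456 with an estimated correlation). When adjusted over the list alone, 0 replication, 2 immediate early and 0 ribosomal genes passed. With fry 1 of the 4 camera calls for the difference of responses held, that of the stress list (fry adjusted p = 0.000484). The replication, immediate early and ribosomal calls were lost without several single arrays, among them shControl_TMZ replicate 3 (adjusted p = 0.0993, 0.0583 and 0.0586). The p53 list did not differ by camera (median 0.00, adjusted p = 0.667), nor did NF-kB targets (0.701), NF-kB components (0.281), mitosis genes (0.0854), base repair genes (0.422), recombination genes (0.701) or interferon genes (0.0751). The same held for the BCL2 family (0.701), mesenchymal (0.701) and proneural markers (0.701), hypoxia (0.701), cholesterol (0.920) and matrix genes (0.701), and leukocyte (0.701) and epithelial markers (0.701). Of these lists, p53 targets and proneural markers each had 1 gene higher and 1 lower adjusted over the list alone, and mesenchymal and epithelial markers 1 higher each.

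No single gene passed in limma for the difference of responses: 0 of 19775 genes, with 1266 at an unadjusted p under 0.05 (6.40%) and 1 by an ordinary linear model. The smallest p belonged to DDIT4, DDIT3, PNLIPRP3, a lipase-related gene, at 0.58 (SE 0.08, adjusted p = 0.104), LINC00520, a noncoding RNA, at 0.53 (SE 0.07, adjusted p = 0.104) and GCNT3, a glycosyltransferase, at 0.50 (SE 0.08, adjusted p = 0.138). CA2, called with TMZ in shp105 cells alone, differed by 0.54 (SE 0.11, adjusted p = 0.381). PLK2 differed by -0.41 (adjusted p = 0.138), KRT7 by 0.75 (adjusted p = 0.138), CDKN1A by 0.04 (adjusted p = 0.962), MDM2 by -0.13 (adjusted p = 0.881), RELA by -0.03 (adjusted p = 0.973) and MGMT by 0.26 (adjusted p = 0.840). With genes below the median level left out 8 genes passed, 6 higher and 2 lower, among them DDIT4 (adjusted p = 0.00782) and DDIT3 (0.0109). Trend and robust fitting gave 12, 9 higher and 3 lower. Among these were DDIT4 (adjusted p = 0.000360), DDIT3 (0.00108), HERPUD1 (0.0204) and GDF15, which differed by 0.49 (0.0204).

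Of the 34 camera calls in the 5 comparisons, 9 held with an estimated correlation: p53 targets, mitosis genes and recombination genes after TMZ in each line, NF-kB targets between the lines under each treatment, and the stress list for the difference of responses. Lists whose median and camera direction differed in sign were all uncalled.

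**Figure D5:**
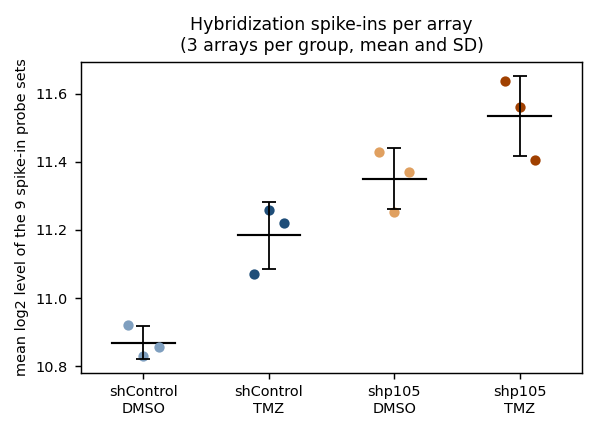
Mean log2 level of the 9 hybridization spike-in probe sets on each of the 12 arrays, by group; points are arrays, bars are group means with SD (n = 3). The means were 10.87 and 11.18 in shControl cells with DMSO and TMZ, and 11.35 and 11.53 in shp105 cells.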

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

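The tests on neighbouring genes, on the DNA replication list, on a shared H2B transcript, on all lists in the regroupings and with the spike-in level as a covariate were chosen only after the result was seen. The other tests of the stress list and the slope on the line difference address patterns seen in the results. They too were not fixed before the data were examined.

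These 4 gene lists stand here because camera found that their TMZ responses differed between the lines. The median differences, shp105 minus shControl, were 0.128 for the integrated stress and unfolded protein response, 0.0769 for ribosomal protein genes, 0.0581 for DNA replication and -0.0588 for immediate early genes. With an estimated correlation the adjusted p stayed under the threshold for the stress list (0.0119) and not for the ribosomal (0.663), replication (0.663) and immediate early lists (0.456). The replication call was lost without any of 7 arrays: shp105_DMSO replicate 1 (adjusted p = 0.188) or 3 (0.0516), shp105_TMZ replicate 3 (0.181), shControl_DMSO replicate 1 (0.200) or 3 (0.0537), and shControl_TMZ replicate 1 (0.0960) or 3 (0.0993). The immediate early call was lost without shControl_DMSO replicate 3 (0.0537) or shControl_TMZ replicate 3 (0.0583), and the ribosomal call without shControl_DMSO replicate 1 (0.0506) or shControl_TMZ replicate 3 (0.0586).

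Hybridization spike-ins, which no comparison of genes uses, differed between the groups. They were higher by 0.415 on shp105 than on shControl arrays (6 against 6 arrays, exact permutation p = 0.00433). TMZ arrays were above DMSO arrays by 0.314 in shControl cells (exact p = 0.1, the smallest that 3 against 3 arrays can give) and by 0.184 in shp105 cells (exact p = 0.2).

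The stress list is the first pattern weighed. Of 100 regroupings of TMZ and DMSO within the lines, 1, the real one, gave a camera p as small for this list. It was 1.89e-10, against 8.21e-05 for the next. Such regroupings also mix the TMZ effect of each line into the groups and their spread. They therefore cannot decide whether the difference between the lines came by chance. The median difference was less apart, 0.128 against 0.116 for the next. With the choice among 19 lists allowed for, 12 of 100 regroupings, the real one included, gave some list a camera p as small. In the others it was the p53 list (10) or the mitosis list (1), which TMZ raised in both lines, so that count mixes in the TMZ effect and leaves open what the choice adds. With the spike-in level as a covariate the median difference was 0.145, not smaller than 0.128, which argues against array brightness relative to the spike-ins. Without any one of the 12 arrays it was at least 0.114 (lowest without shControl_TMZ replicate 1) and at most 0.166, which argues against a single array. A difference in RNA quality stays open: ribosomal protein genes shifted the same way, and the 3' minus 5' signal of ACTB changed by -0.17 with TMZ in shControl cells (exact p = 0.1) but by -0.01 in shp105 cells (exact p = 1). The 3' minus 5' signal of GAPDH changed by 0.05 with TMZ in shControl cells (exact p = 0.1) and by 0.04 in shp105 cells (exact p = 0.4). A change of the stress response by the hairpin stays open beside RNA quality, untested.

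The pattern next weighed is that 3937 genes differed between the lines in DMSO while NFKB1 differed by -0.12. Spike-ins were also higher on the TMZ than on the DMSO arrays of shControl cells. If array brightness relative to the spike-ins made the pattern, the 350 genes at 2-fold or more would shift with TMZ too. Their slope on the line difference would be near 0.654. The slope was 0.0276 (SE 0.00542), and the arrays both share would push it upward, so the tables argue against such brightness for these genes. Broad copy-number differences as the cause of most of these differences would shift neighbouring genes together by about their median size of 0.36, but the largest median of 60 neighbours was 0.143 in size. Neighbours were still more alike than in 1000 shuffled gene orders, for that median (p = 0.0230) and for their correlation (rho 0.0494, at most 0.0274 when shuffled, p = 0.001, the smallest that the shuffles can give), but so were they in the TMZ responses within a line, where no copy-number difference between lines enters (rho 0.0527 in shControl and 0.0728 in shp105 cells, p = 0.001 each; p = 0.0120 and 0.0300 for the largest median). The likeness therefore does not point to copy number, and smaller or narrower copy-number differences stay open. The hairpin itself and other differences between the stably transfected populations stay open, untested, since the labels do not tell separate transfections apart. No label gives a hybridization batch, so none was tested, and the slope speaks only for the genes at 2-fold or more.

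The last pattern weighed is the lower level of 9 of 14 H2B histone transcripts in shp105 cells with DMSO. A single H2B transcript read by several probe sets stays open: the median correlation of the 9 genes between arrays of a group was 0.0724. A low correlation decides nothing here, since replicate arrays need not vary in a shared transcript. Fewer cells in S phase stays open: the DNA replication list was lower too, with a median of -0.156 (bootstrap 95% interval -0.235 to -0.0854) against -0.496 for the H2B genes, and how far each would fall was not measured. Whether the lines differ in polyadenylated histone transcripts was not tested.

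Other splits of the same arrays were tried for each count of genes. For TMZ in shControl cells, TMZ in shp105 cells, and the lines in DMSO and in TMZ, 1 of 10 splits, the real one, gave as many genes (73, 171, 3937 and 4166 against a highest other count of 0), and 10 splits are too few for a share under 0.05. For the difference of responses, with 0 genes called, 100 of 100 regroupings gave as many, with a highest other count of 2; since no regrouping can give fewer than 0, this says nothing about chance.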

How the results depend on the processing

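The fit with the spike-in level as a covariate, the scaling and left-out arrays for gene lists and the left-out arrays for similarities were chosen after seeing the data. No called value of a named gene reversed: of 246 such values, 104 kept their call with the spike-in covariate and 142 lost it, 192 kept it with only the compared groups in the fit, 208 with the mean of probe sets, 219 with the replicate block, 231 with median centring or the ordinary linear model, 232 with array weights, and 245 with quantile normalization or trend and robust fitting. All 191 that remain with genes below the median level left out kept it. With each array left out, 234 of 1476 values lost their call. Counts, given here for TMZ in shControl cells (73) and then in shp105 cells (171), became 15 and 39 at an adjusted p under 0.01, 19 and 16 at 1.5-fold or more, 291 and 904 with genes below the median level left out, 149 and about 1.1e+02 (80 higher, 25 lower) with array weights, 358 and 937 with trend and robust fitting, 115 and 333 with an ordinary linear model, 19 and 2 with only the compared groups, 30 and 84 with the replicate block, and 0 and 7 with the spike-in covariate. For the first the mean of probe sets gave 45 and median centring 43; for the other each probe set on its own gave 101. Between the lines in DMSO (3937) and TMZ (4166), the stricter adjusted p gave 2439 and 2566, 1.5-fold 911 and 935, each probe set on its own 6590 and 7014, and the spike-in covariate 483 and 997. For the difference of responses (0), 8 genes passed with genes below the median left out, 12 with trend and robust fitting and 1 with an ordinary linear model. The similarity r rose from 0.33 to 0.60 for TMZ and from 0.90 to 0.95 for the lines with genes below the median left out. Stricter thresholds call fewer genes by construction, each probe set on its own counts probe sets, and the covariate raised the standard errors; for the rest the cause was not tested. With 1 array left out the counts ranged from 16 to 29, 49 to 188, 3042 to 3369, 3219 to 3778 and 0 to 0, and r from 0.26 to 0.36 and 0.88 to 0.89. The counts for TMZ moved by over 1.5 times without shControl_DMSO replicates 1 (29), 2 (16) and 3 (20), shControl_TMZ replicates 1 (24), 2 (16) and 3 (19), shp105_DMSO replicates 1 (52), 2 (49) and 3 (76), and shp105_TMZ replicates 2 (81) and 3 (86). The replicate numbers do not pair the samples: deviations of same-numbered arrays correlated at -0.14 to 0.12 (median 0.02), 2 of 18 above 0.1, and 4 of 12 arrays matched their own number best. The block gave 3677, 3885 and 0 genes for the other comparisons. Of 34 list calls, 9 held with an estimated correlation, 30 with fry, 33 with the block, 29 with genes below the median left out, 27 with the mean of probe sets, 32 with median centring, 31 with quantile normalization and 27 with the spike-in covariate. Signal over background limits dim genes: 97.5% of values of 27 control probe sets lay below 4, and among called genes 122 (DMSO) and 143 (TMZ) between the lines had 1 group below that level and 94 and 159 both, so the sizes of such differences start from or stay within background.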

Other observations

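The families in this part were chosen only after their values were seen. No enrichment was tested, and over all 19775 genes 2287 were lower and 1650 higher in shp105 cells with DMSO, and 2173 lower and 1993 higher with TMZ. The counts that follow had the same direction under median centring and quantile normalization. Of 43 replication-dependent histone genes 21 were lower and 1 higher in shp105 cells with DMSO, and 14 lower (15 with median centring) and 1 higher with TMZ. H2BC12 was at -2.67 and -2.47, and the higher gene, H2AC6, at 3.03 and 2.53, from a background level of 3.80 and 3.86 in shControl cells. Of 9 HOXC genes, which set positional identity, 5 were lower under either treatment (6 with either scaling in TMZ), among them HOXC4 at -2.57 and -2.42 and HOXC6 at -1.72 and -1.67; 4 of 10 HOXB and 4 of 8 HOXD genes were lower as well, and 0 were higher. Of 30 cancer-testis genes 13 were higher and 3 lower with DMSO (12 higher with median centring) and 13 higher and 2 lower with TMZ. SSX3 was at 2.96 and 2.95 and MAGEC2 at 1.78 and 1.74, against MAGEC1 at -2.24 and -2.23.

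Of 15 MHC class II genes 8 were lower in shp105 cells under either treatment, with HLA-DRA at -1.88 and -1.66. Single genes picked one by one for their values were lower too. The growth factor CSF3, at -2.67 and -2.35, and the inflammasome sensor NLRP3, at -1.49 and -1.73, stand for no group. The others belong to the NF-kB target list and are already part of its result above. They were the prostaglandin synthase PTGS2 at -1.66 and -1.56, the cytokine IL6 at -1.27 and -1.02 and the adhesion gene ICAM1 at -1.01 and -0.88. The chemokine CCL2, of the same list, was at -1.33 and -1.24, down to a background level of 3.35 and 3.32. Of 9 pregnancy-specific glycoprotein genes 6 were higher and 0 lower, and PSG1 and PSG7 also rose with TMZ in shp105 cells by 0.45 and 0.60. The stress genes NUPR1 and PCK2 rose with TMZ in shp105 cells by 0.48 (adjusted p = 0.0154) and 0.37 (adjusted p = 0.0347). Their differences from the response of shControl cells were 0.47 (adjusted p = 0.475) and 0.41 (adjusted p = 0.510).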
